A study of Mus musculus with 3 samples.

How the data were processed

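Total RNA from sorted hematopoietic stem cells was labelled with Cy3 and hybridised to one-colour Agilent mouse arrays, per the labels' protocols. The cells came from the pooled marrow of 20 mice and were either lysed at 0 h or cultured for 16 h without serum or with 10% serum. The 3 arrays, 1 per condition, share 1 slide and 1 scan and have the design number 028005, scanned at 3 micron, per the file headers. No slide or scan therefore separates the conditions. Culture, RNA extraction and labelling can each differ with condition, and this could not be tested. The submitters' processing notes name Agilent Feature Extraction 9.5.3, while the file headers give version 11.5.1.1. The difference stays open.

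The deposited scanner files hold, for each of 62976 spots, a processed intensity (background-subtracted and detrended, on a linear scale, with surrogate values for dim spots), its error, the raw mean and local background intensities, and flags, per the file headers. The authors also deposited a table of log2 values. Each column of it follows the log2 processed signal of its own array minus the 75th percentile, with a correlation of 1.00 and a largest absolute difference of 0.01, so that its scale, centring and direction are known. Its column medians were -2.36, -2.46 and -2.46 for the fresh, serum-free and serum arrays. It was used as an alternative source of values.

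For the main setting, control spots and spots marked as non-uniform or population outliers (153, 176 and 159 spots on the fresh, serum-free and serum arrays) were left out. The log2 processed signals of the spots of a probe were averaged, and the array's 75th percentile over 55667 probes was subtracted. No spot was saturated. A probe counted as detected where most of its spots carried the flag for a signal well above background. Per the file headers, that flag uses a multiplier of 13 on a background error. It was set on 0.649%, 1.95% and 1.62% of 308 negative control spots on the fresh, serum-free and serum arrays. Of 137 spike-in control probes, 43, 26 and 31 carried it, and the labels do not say whether spike-in RNA was added. The median processed signal was 31.8, 31.1 and 30.4 intensity units on the 3 arrays.

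Probes were named by matching the accession given in the files, without its version, to a RefSeq gene table of assembly GRCm38.p6 (28026 probes). Otherwise the symbol (3418) or an unambiguous synonym (295) was matched. The remaining 23942 probes kept the name in the files and stayed out of gene counts, and 16194 of them read genomic intervals. The array's annotation uses mm9, per the file headers. Coordinates are those of the probes in the files, and the exon or UTR a probe lies in was not determined, since no annotation of that build was used here. In all, 22563 genes had a probe and 16708 had a detected one. A gene was represented by its probe with the highest mean signal among those detected on at least 1 array. Of these genes, 4901 had more than 1 detected probe. The median standard deviation of a difference between probes of 1 gene was 0.38 for serum-free minus fresh, 0.37 for serum minus fresh and 0.26 for serum-free minus serum. Where probes of a named gene disagree in sign, both values are given.

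With 1 array per group there is no spread between replicates, so no test was made and no p-value is given. Genes detected on both arrays of a comparison counted as measured, and those at least 2-fold different were counted. A gene detected on 1 array, with no probe detected on the other, has only a bound, written as at least N-fold. It sets the bright signal against the higher of the dim array's lowest detected signal and the dim probe's own signal. Of each gene list, the median difference was set against 10000 random lists of the same size drawn with replacement from the same 20 bins of mean signal, as a description of these arrays. The range given is their middle 95%. The overlap of both differences against the fresh array was compared with 100 simulations of unchanged arrays that carry the scatter of the serum-free minus serum difference.

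The 32 gene lists, with 582 entries of which 2 had no probe, and the rule for naming genes were fixed before the data were examined. The lists cover lipid metabolism (fatty acid synthesis, cholesterol synthesis and uptake, fatty acid oxidation, fatty acid uptake and storage, LXR targets), stem cell state, cell cycle, metabolism and stress, signalling, and markers of other cell types the sort could hold. Named genes are, per comparison, the 6 with the largest difference in each direction among measured genes brighter than the median with a proper symbol, the 3 largest bounds in each direction, and 2 to 4 members of each list with the largest differences. All members of the fatty acid and cholesterol synthesis lists and 10 sort marker and HSC genes could also be named. Genes named outside this rule are marked as chosen after their values were seen. The bounds of neutrophil list members are given without this mark.

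The alternatives were quantile normalization, median scaling, scaling on probes detected on all arrays, normexp background correction (offset 50), the authors' deposited log2 values, no filter on dim probes, the brighter part of the genes, the mean over a gene's probes, a 3-fold threshold and random lists without matching. After the data were seen, 3 more were added, namely counts over all named targets, list members at their bound, and a correction for probe GC content and signal. The counting and list steps were tested on simulated data for serum-free minus fresh with 13479 genes, of which 225 were changed, 25 of them as a list shifted 2-fold. They recovered 100 of 100 genes changed 4-fold and 100 of 100 changed 8-fold, and 1.55% of unchanged genes passed 2-fold. The simulated noise had a standard deviation of 0.29 (log2) per array, taken from the scatter between both cultured arrays, and the real detection flags were kept. The measured serum-free minus fresh difference had a standard deviation of 0.91. These shares therefore check the steps and are not error rates for the measured differences. Of 200 unchanged lists of 25 genes, 6 fell outside the random range. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for normexp, were used.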

Results

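The study measured gene expression in mouse hematopoietic stem cells (HSCs), the rare bone marrow cells that sustain blood formation. The cells carried the surface profile CD150+ CD41- CD48- CD34- Flt3- within the lineage-negative, Sca-1 and Kit positive (LSK) fraction. They came from the pooled marrow of 20 male C57BL/6J mice aged 10 weeks. One portion was lysed fresh at 0 h. The others were cultured for 16 h in SF-O3 medium with 100 ng/mL stem cell factor (SCF) and 100 ng/mL thrombopoietin (TPO), either without serum or with 10% serum. Each of the 3 conditions was measured on 1 one-colour Agilent array, so no comparison has a replicate. No difference below was tested, and genes are described as higher or lower by the size of the difference alone. All 3 arrays lay on 1 slide and were scanned together.

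Of 55667 probes used, 64.6% were well above background on the fresh array, 56.4% on the serum-free array and 60.7% on the serum array. In genes, 15766 were detected on the fresh array, 13992 on the serum-free array and 14850 on the serum array. Levels are log2 signals relative to the 75th percentile of the same array. Spots of the same probe on 1 array had a median standard deviation of 0.10, 0.09 and 0.09 (log2) on the fresh, serum-free and serum arrays. The scanner software's own error for a difference between 2 arrays had a median of 0.21 (log2), and this is the error given with ± below. It covers the array measurement only and not the spread between cultures or animals. Lists with medians inside the random range described below are called neither higher nor lower. The number of arrays limits the precision of every value.

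The first comparison, serum-free culture against fresh cells, addresses how HSC transcripts differ after 16 h of serum-free culture, including those of fatty acid synthesis. Time in culture, medium, SCF and TPO changed together against the fresh cells, here and in the second comparison, and cannot be told apart. Genes of cholesterol synthesis and uptake and of fatty acid synthesis were higher after serum-free culture, cell cycle genes were higher, and immediate early genes were lower. The HSC identity list had a median below 0, with only part of its members at least 2-fold lower. In the cholesterol list, 19 of 25 measured genes were at least 2-fold higher and 0 were at least 2-fold lower, with a median difference of 1.60 (quartiles 1.00 and 2.20). The largest differences were for Fdps (2.82 ± 0.20), which makes farnesyl diphosphate, Pmvk (2.64 ± 0.20) and Hmgcs1 (2.40 ± 0.20), which act in the mevalonate pathway, and Pcsk9 (2.39 ± 0.36), which lowers LDL receptor levels. In the fatty acid synthesis list, 14 of 27 genes were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.23 (quartiles 0.47 and 1.90). Scd1, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, was 29.3-fold higher (4.87 ± 0.21). Its paralog Scd2 was 6.54-fold higher (2.71 ± 0.20), and the elongases Elovl6 and Elovl1 differed by 2.22 and 2.20. Fasn, the fatty acid synthase, differed by 1.93 ± 0.31 but was dim (level -3.12 on the fresh array) and was below 2-fold with normexp background correction (0.71). Acly, which supplies cytosolic acetyl-CoA, differed by 1.78 ± 0.20. The fatty acid list's median was 0.79 with normexp. Neutrophil and monocyte markers differed between these arrays as well, with Camp at -3.55.

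The probe for Scd1 lies on chromosome 19 from 44469387 to 44469446 and that for Scd2 on chromosome 19 from 44381024 to 44381083, both in the mm9 build that the files use. Fasn is read by a probe on chromosome 11 from 120667666 to 120667725, and Ldlr by a probe on chromosome 9 from 21554286 to 21554345.

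Other lipid lists differed less between serum-free and fresh cells. The median for fatty acid oxidation was -0.14, inside the middle 95% of random lists matched on signal (-0.29 to 0.43). Its members with the largest differences were Pdk4 (-1.89), a kinase that inhibits pyruvate dehydrogenase, and Cpt1a, which carries fatty acids into mitochondria and gave -1.63 with its brightest probe and 0.99 with another. Fatty acid uptake and lipid storage genes had a median of -0.40 with 2 of 17 members at least 2-fold higher and 2 at least 2-fold lower, and the median turned to 0.05 in the brighter part of the genes. Targets of the sterol receptor LXR had a median of -0.15, with Arl4c at -3.57, Smpdl3a at -2.19 and Lpcat3 at 1.47. Abca1, named after its value was seen and outside that median, was at least 9.84-fold lower.

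Immediate early genes, which are transcribed within minutes of a stimulus, showed the largest list difference. All 11 members measured on both arrays were at least 2-fold lower after serum-free culture, with a median of -5.51. Fosb differed by -10.42 ± 0.22, Jun by -8.23 ± 0.25, Nr4a1 by -8.03 ± 0.26 and Dusp1 by -6.58 ± 0.20, with smaller values for Fosb (-9.54), Jun (-6.86) and Nr4a1 (-6.59) under normexp. Fos was at least 776-fold lower and Klf4 at least 318-fold lower, since both were detected on the fresh array only. Quiescence and cell cycle inhibitor genes had 11 of 15 members at least 2-fold lower (median -1.55), among them Klf6 (-4.57), Btg1 (-3.51) and Tob1 (-3.46). Klf2 was at least 930-fold lower. Inflammatory NF-kB genes had a median of -1.49 with 7 of 12 members at least 2-fold lower, led by Tnfaip3 (-3.91) and Ccl4 (-3.74), and the median was -0.73 without the filter on dim probes and -0.90 with normexp. Some members of this list, named after their values were seen, went the other way. Ccl5 was higher (1.95), and Tnf and Cxcl10 were at least 6.68-fold and 8.98-fold higher, while Icam1 was at least 2.37-fold lower. Rhob (-6.29, or -3.38 with its other probe) and Zfp36 (-5.59), an mRNA decay factor, were also among the 6 bright genes with the largest negative differences.

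HSC identity genes had a median of -0.90, with 12 of 30 members at least 2-fold lower. The 2 members at least 2-fold higher, named after their values were seen, were Ly6a (1.55), which encodes the sort marker Sca-1, and Mycn (1.26). The largest differences were for Sult1a1 (-2.67), the receptor Tek (-2.43), Robo4 (-2.34) and Vwf (-1.56). Among genes fixed beforehand for this purpose, Procr differed by -0.67, Hlf by -0.95, Kit by -0.77 and the thrombopoietin receptor Mpl by -0.22. Mecom gave -1.20 with its brightest probe and 0.01 with another. The sort markers Slamf1 (CD150) at -1.38 ± 0.35 and Cd48 at -0.22 ± 0.35 were dim on both arrays, Itga2b (CD41) differed by -0.01, and Cd34 by -0.68 or 0.15 according to the probe. Multipotent progenitor markers had a median of -0.23 over 4 measured members. The 3 members with a bound were all lower, Flt3 at least 4.03-fold and, named after their values were seen, Sell at least 3.13-fold and Satb1 at least 5.49-fold. With these members the median was -0.68.

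Cell cycle genes were higher after serum-free culture, and lists of growth and energy metabolism had medians above 0. The G2/M list had 14 of 20 members at least 2-fold higher (median 1.80), led by Cenpe (2.95), Kif11 (2.70), Cdk1 (2.70) and Top2a (2.47). The G1/S list had 15 of 25 (median 1.12), led by Rrm2 (2.85), the ribonucleotide reductase subunit, and Tk1 (2.48). Oxidative phosphorylation genes had a median of 0.82 with all 25 members above 0 and 8 at least 2-fold higher, and ribosome biogenesis and MYC target genes a median of 0.82 with 10 of 26 at least 2-fold higher. Glycolysis genes had a median of 0.62, led by Pgk1 (1.81), while hypoxia (HIF) targets had a median of -0.45, led by Vegfa (-2.07). Higd1a (1.55) and Ero1a (1.20) of the HIF list were higher. NRF2 and antioxidant genes had a median of 1.07, led by Nqo1 (3.25), and ER unfolded protein response genes 0.74, although Dnajb9 was at -2.95. Type I interferon genes had a median of 1.03 with 8 of 15 members at least 2-fold higher, led by Isg15 (3.11) and Irf7 (2.30). Ifit3 was at least 21.7-fold higher.

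Of the remaining lists in this comparison, p53 targets (-0.62, led by Plk2 at -4.07) and TGF-beta and BMP targets (-0.88, led by Skil at -4.17) had medians outside the random range. ATF4 amino acid response genes (0.46), cytosolic heat shock genes (0.22), cytokine feedback genes (-0.24) and SRF and YAP serum response genes (0.09) did not. Members of the p53 list, named after their values were seen, went both ways. Bax (1.62) and Aen (1.13) were higher and Phlda3 at least 11.2-fold higher, while Perp (-2.98) was lower and Btg2 at least 36.0-fold lower. Cdkn1a gave values from -2.03 to 2.00 with its 3 probes. The 6 bright genes with the largest positive differences were the beta-globin gene Hbb-bt (5.29), the calcium-binding protein gene S100a4 (4.95), Scd1, the mitochondrial folate enzyme gene Mthfd2 (4.05), the nuclear pore gene Nup43 (3.39) and the antiviral gene Oas3 (3.38). Globin probes are uncertain, since beta-globin genes are near-identical in sequence. Afp and H2-DMb2 were at least 27.8-fold and 20.2-fold higher.

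Markers of other blood cells differed between the arrays as well. The lineage-negative LSK gate is meant to exclude such cells, and whether these transcripts came from cells that passed it or from the HSCs was not separated. The neutrophil and monocyte list had a median of -0.41 over the 8 members measured on both the serum-free and fresh arrays, and another 7 members were detected on the fresh array only. With those at their bound the median was -2.58. S100a9 was at least 260-fold lower and S100a8 at least 30.8-fold lower on the serum-free array, and the granule protease gene Prtn3 differed by -2.64. The brightest members of that list, named after their values were seen, differed little. Csf3r and Csf1r were each at -0.10, and Itgam gave 0.08 with its brightest probe and -0.63 with another. Megakaryocyte markers had a median of -0.90 (Treml1 -2.91, Gp1ba -1.82), although Pf4 was 2.79-fold higher. Ppbp, named after its value was seen, was at least 3.93-fold higher. Erythroid markers had a median of -0.07 over 8 members (Alas2 2.34, Gata1 -2.25), with -1.48 over the 3 in the brighter part of the genes. B cell (-0.03), T and NK cell (0.10) and stromal and endothelial (0.05) markers had medians inside the random range over 3, 4 and 6 measured members. Mast cell and basophil markers had fewer than 3 measured members.

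In all, 1667 of 13484 genes measured on both arrays were at least 2-fold higher after serum-free culture and 1305 at least 2-fold lower. Another 301 and 489 genes had bounds of at least 2-fold higher and lower. Normexp background correction gave 906 and 687 genes. The balance depended on the setting, since higher genes made up 56.1% of these differences, 47.2% when arrays were scaled on probes detected on all 3 arrays and 44.3% without the filter on dim probes. Among named genes, normexp took Pcsk9 (0.84), Gp1ba (-0.73) and Slamf1 (-0.52) below 2-fold, and the mean of probes did so for Cpt1a (-0.32) and Mecom (-0.07). Normexp also gave smaller differences, still past 2-fold, among others for Scd1 (4.19), Elovl1 (1.03), Cenpe (1.67), Tob1 (-1.81), Arl4c (-2.16), Tnfaip3 (-2.56), Skil (-2.90) and Mthfd2 (3.09).

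The second comparison, culture with 10% serum against fresh cells, addresses the same question in the presence of serum. Cell cycle and ribosome biogenesis genes were higher, immediate early and quiescence genes were lower, and cholesterol synthesis genes stayed near their fresh levels as a group. The HSC identity list had a median below 0, with only part of its members at least 2-fold lower. The cholesterol list had 2 of 25 members at least 2-fold higher and 4 at least 2-fold lower, with a median of -0.08 inside the random range (-0.27 to 0.42) and at 0.12 in the brighter part of the genes. Insig1, which retains SREBP in the endoplasmic reticulum, differed by -1.99 ± 0.22 and Tm7sf2 by -1.57, while Pcsk9 (1.81) and Ebp (1.41) were higher. The fatty acid synthesis list had 7 of 27 members at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.46 just outside the random range (-0.26 to 0.43). Elovl1 (2.21) and Hsd17b12 (1.78) were higher, whereas Scd1 was 3.02-fold lower (-1.60 ± 0.26, or -0.72 with normexp). Scd2 differed by 0.03 (from -0.22 to 0.12 over the alternatives) and Fasn by 0.65 ± 0.33. LXR targets had a median of -1.17 with 4 of 8 members at least 2-fold lower, among them Arl4c (-2.18), Smpdl3a (-2.11) and the sterol transporter gene Abcg1 (-1.82). Abca1, named after its value was seen and outside that median, was at least 12.3-fold lower. Fatty acid uptake and storage genes had a median of -0.44, with Hilpda at 2.40 and Lpl, the lipoprotein lipase gene, at 2.10. Fatty acid oxidation genes had a median of 0.01, with Pdk4 at -3.08.

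All 13 measured immediate early genes were at least 2-fold lower with serum (median -4.65), including Fosb (-10.42 ± 0.21), Jun (-8.14 ± 0.23), Dusp1 (-6.29) and Nr4a1 (-6.26). Fos and Klf4 were at least 968-fold and 396-fold lower, and the heat shock gene Hspa1a at least 69.9-fold lower. Quiescence genes had a median of -1.78 with 11 of 16 members at least 2-fold lower, led by Klf2 (-9.26 ± 0.28) and Klf6 (-5.05). Rhob differed by -5.72, or -3.34 with its other probe. NF-kB genes had a median of -0.92, which was -0.27 without the filter on dim probes and -1.63 with the mean of probes. Members of this list went both ways, as named after their values were seen. Tnfaip3 (-3.84) and Ccl4 (-3.36) were lower and Icam1 at least 2.96-fold lower. Traf1 (1.62) and Ccl5 (1.15) were higher, and Tnf and Cxcl10 at least 11.1-fold and 6.31-fold higher. HSC identity genes had a median of -0.85 with 12 of 29 members at least 2-fold lower and 2 at least 2-fold higher. The 2 higher members, named after their values were seen, were Ly6a (1.70) and Mycn (1.43). The lower members were led by Pdzk1ip1 (-3.49, or -1.86 with its other probe), Hoxb5 (-2.44) and Tek (-2.36). Procr differed by -0.71, Hlf by -0.68, Kit by -0.61 and Mpl by -1.08. Mecom gave -0.61 and -0.13 with the 2 probes measured on both arrays, and 0.14 as the mean over 3 probes, which includes a probe not detected on the fresh array. Cd34 gave 0.01 and 1.09 with its 2 probes, Flt3 gave -1.20 and 0.47, Cd48 differed by -0.08 and Itga2b by 0.33. Slamf1 was at least 3.94-fold lower.

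The G2/M list had 17 of 20 members at least 2-fold higher with serum (median 2.01), led by Cdk1 (3.07, or 0.46 with its lowest probe), Cenpe (3.02) and Ccnb1 (2.95), and the G1/S list 16 of 25 (median 1.11), led by Rrm2 (3.10) and Tk1 (2.89). All 26 ribosome biogenesis and MYC target genes were above 0, and 16 of them at least 2-fold higher (median 1.18), led by Polr1b (2.20) and Nop16 (1.94). Medians outside the random range were also seen for oxidative phosphorylation (0.92), glycolysis (0.78, although Aldoc was at -3.30), ATF4 amino acid response (0.75, or 0.33 without the filter on dim probes, led by Mthfd2 at 4.86), ER unfolded protein response (0.67), NRF2 and antioxidant (0.85) and p53 target genes (-0.52). Within the p53 list, named after their values were seen, Plk2 (-4.88) was lower while Zmat3 (1.64) and Bax (1.55) were higher. Type I interferon genes had a median of 0.38, inside the random range, with 2 of 14 members at least 2-fold higher and 2 at least 2-fold lower. Cytosolic heat shock (0.38), HIF target (-0.24), cytokine feedback (-0.31), SRF and YAP (0.10) and TGF-beta and BMP target (-0.53) genes also had medians inside it. The bright genes with the largest positive differences were Hbb-bt (5.83), S100a4 (4.95), Mthfd2, the ribosome assembly gene Bysl (3.50), Nup43 (3.37) and the mitotic gene Cdca3 (3.28). The granzyme gene Gzmb was at least 56.1-fold higher, Hbb-b2 at least 25.2-fold and the mitotic helicase gene Ercc6l at least 23.1-fold.

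The neutrophil and monocyte list was lower than in fresh cells on this array too, though not in all members. Of 14 measured members, 9 were at least 2-fold lower, with a median of -1.54, led by Ngp (-2.59), Prtn3 (-2.59), Mpo (-2.37) and Camp (-2.17). With normexp that median was -0.75. The brightest members, named after their values were seen, differed little. Csf3r was at -0.20, Itgam gave 0.30 with its brightest probe and -0.22 with another, and Csf1r -0.23 and 0.34. Ms4a3 (0.38) and Fcgr3 (0.55) were above 0. Erythroid markers had a median of -0.81 (Gata1 -1.77), megakaryocyte markers -0.34 (turning to 0.23 without the filter on dim probes and 0.33 in the brighter part of the genes), multipotent progenitor markers -0.08, B cell markers -0.45, T and NK cell markers 0.05 and stromal and endothelial markers -0.14. The multipotent progenitor members with only a bound, named after their values were seen, were both lower, Satb1 at least 6.84-fold and Ccr9 at least 3.08-fold.

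With serum, 1899 of 14057 genes measured on both arrays were at least 2-fold higher than in fresh cells and 1513 at least 2-fold lower, and 329 and 439 further genes had bounds of at least 2-fold higher and lower. Normexp background correction gave 1128 and 794 genes. Higher genes made up 55.7% of these differences, 44.5% when arrays were scaled on probes detected on all 3 arrays and 46.0% without the filter on dim probes. Among named genes, normexp took Elovl1 (0.85), Pcsk9 (0.54), Tm7sf2 (-0.54) and Flt3 (-0.52) below 2-fold and Lpl to its edge (1.00), and median scaling put Mpl at -0.98. Normexp gave smaller differences, still past 2-fold, among others for Fosb (-9.53), Klf2 (-7.51), Jun (-6.82), Pdzk1ip1 (-1.80), Pdk4 (-1.42), Cenpe (1.74), Aldoc (-2.30) and Mthfd2 (3.82).

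The third comparison sets both cultures side by side at 16 h and addresses the difference that serum makes, above all to fatty acid synthesis. Cholesterol synthesis genes were higher without serum, as were type I interferon genes. The fatty acid synthesis list had a median above 0 with 8 of 27 members at least 2-fold higher. TGF-beta and BMP targets had a median below 0 with 3 of 9 members at least 2-fold lower, and ribosome biogenesis and G2/M lists had medians below 0 with few members past 2-fold. The cholesterol list had 21 of 25 members at least 2-fold higher without serum and 0 at least 2-fold lower, with a median of 1.90 (quartiles 1.15 and 2.27), or 1.28 with normexp. Hmgcs1 was 6.76-fold higher (2.76 ± 0.20), Pmvk 5.66-fold and Nsdhl 5.48-fold (2.46 ± 0.21), although another Nsdhl probe gave 1.03. Lss (2.59), Fdft1 (2.45), Ldlr (2.23 ± 0.20), the receptor that takes up LDL cholesterol, and Hmgcr (1.91 ± 0.20), the rate-limiting enzyme of the pathway, were higher too. Only Acat2 (-0.12) and Ebp (-0.15) were below 0. Both probes of Mvk disagreed in sign (1.67 and -0.72). The fatty acid synthesis list had 8 of 27 members at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.75 (quartiles 0.05 and 1.17). Both medians lay above all 10000 signal-matched random lists.

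Scd1 showed the largest difference between the media among bright genes, at 88.7-fold higher without serum (6.47 ± 0.25). Its level was 3.90 on the serum-free array, -0.98 on the fresh array and -2.57 on the serum array, where it was dim, and the difference was 4.91 with normexp background correction. Scd2 was 6.40-fold higher without serum (2.68 ± 0.20). Acss2 (1.74), Slc25a1 (1.35), Fads2 (1.34), Acly (1.32) and Fasn (1.28 ± 0.27) were at least 2-fold higher, but Fasn was dim on both arrays (levels -1.19 and -2.47) and was below 2-fold with normexp (0.55). Acaca, the acetyl-CoA carboxylase that commits carbon to fatty acids, differed by 0.46, with -0.03 from another of its probes. Elovl1 (-0.01, or 0.18 with its other probe) and Hsd17b12 (0.01), both higher in culture, differed little between the media. Srebf1 and Srebf2, which encode the SREBP transcription factors, each differed by 0.52, although the other Srebf2 probe gave -0.20.

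**Figure D1:**
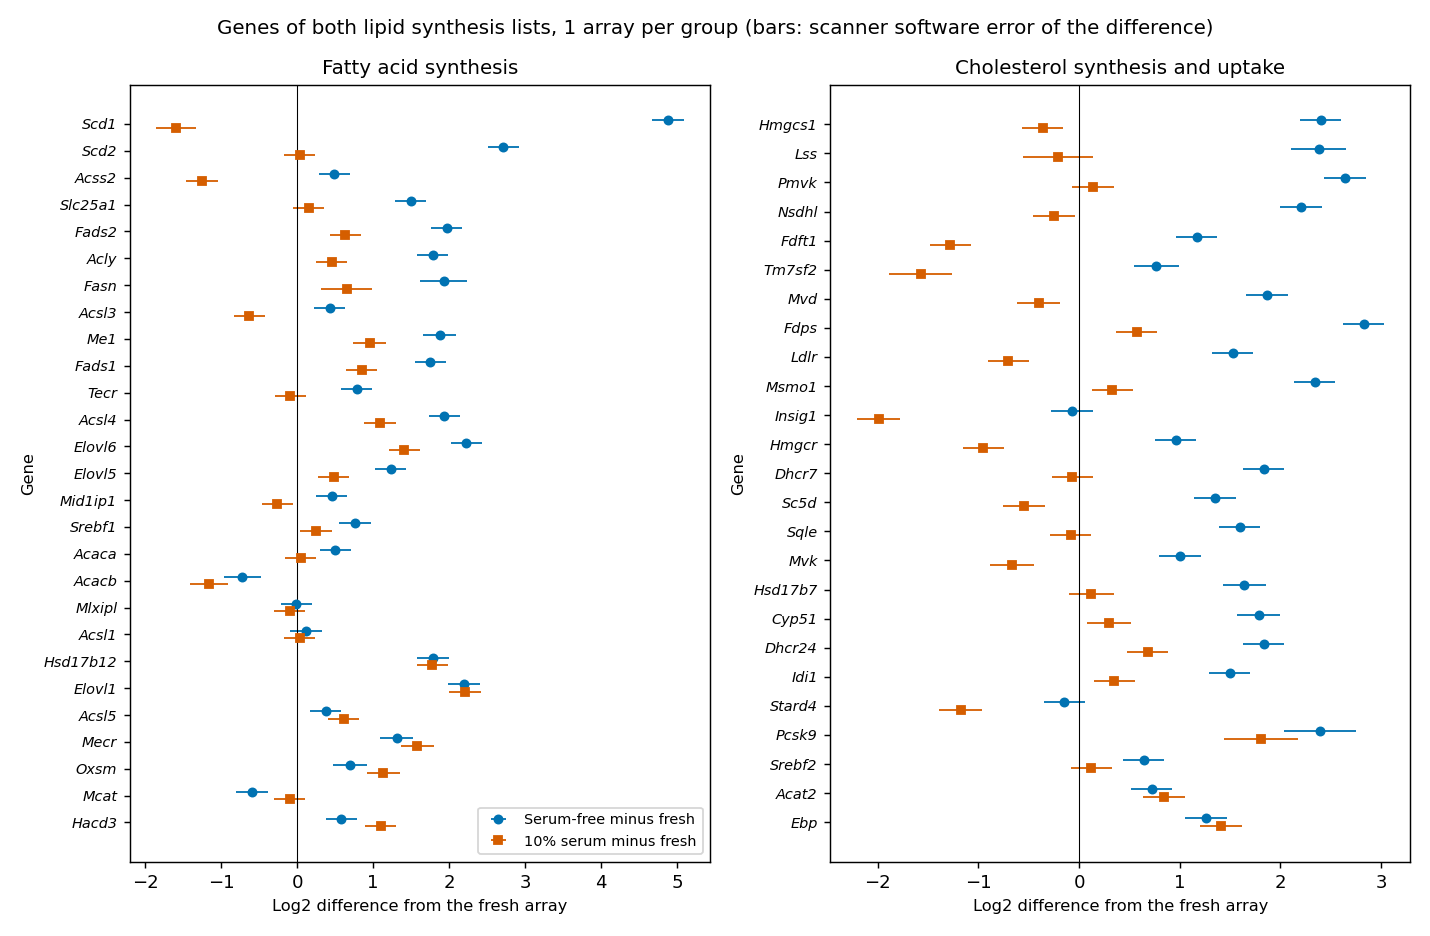
Log2 difference from the fresh array (horizontal axis) for each gene of the fatty acid synthesis list (27 genes) and the cholesterol synthesis and uptake list (25 genes), for the serum-free array (blue circles) and the 10% serum array (orange squares), with bars for the scanner software's error of the difference. Genes are ordered by the difference between the media, from Scd1 (4.87 without and -1.60 with serum) at the top of the left panel and Hmgcs1 (2.40 and -0.36) at the top of the right panel.

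Fatty acid oxidation (-0.04) and fatty acid uptake and storage genes (-0.04) had medians inside the random range between the media. LXR targets had a median of 0.45, or 0.97 in the brighter part of the genes, with Abcg1 at 1.87 and Arl4c at -1.39. Type I interferon genes had a median of 1.13 with 9 of 16 members at least 2-fold higher without serum, led by Oasl2 (2.62 ± 0.21), Ifi44 (2.33), Isg15 (2.11) and Irf7 (1.89). Oasl2 and Isg15 are induced by interferon, and Irf7 is a transcription factor of that response.

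Ribosome biogenesis and MYC target genes had a median of -0.43 with 23 of 26 members below 0 but only 2 at least 2-fold lower, led by Pes1 (-1.16), Polr1b (-1.05) and Myc (-0.93), although other probes of Pes1 and Polr1b gave 0.34 and 0.65. G2/M genes had a median of -0.31 with 19 of 21 members below 0 and 0 at least 2-fold lower, and ATF4 amino acid response genes -0.30, whereas G1/S genes had a median of -0.09 inside the random range. TGF-beta and BMP targets had a median of -0.52 with 3 of 9 members at least 2-fold lower, led by Skil (-2.22), Tgfbi (-2.13) and Id2 (-1.36). Glycolysis genes had a median of -0.20, although Aldoc (3.88) and Slc16a3 (1.71) were higher without serum. NRF2 and antioxidant genes had a median of 0.16.

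The remaining lists had medians inside the random range between the media. These were HSC identity (-0.05), quiescence (0.16), immediate early genes (0.00), HIF targets (-0.07), oxidative phosphorylation (-0.01), ER unfolded protein response (-0.01), heat shock (-0.14), p53 targets (0.10), cytokine feedback (-0.22), SRF and YAP serum response (-0.18) and NF-kB genes (-0.20). Within the HSC identity list, Pdzk1ip1 (2.01) and Hoxb5 (2.14-fold) were higher without serum, and Txnip gave 1.04 and -0.23 with its 2 probes. Mpl differed by 0.85, Procr by 0.04, Hlf by -0.27, Kit by -0.16, Cd34 by -0.69, Cd48 by -0.14 and Itga2b by -0.34. Mecom gave values from -0.59 to 0.14 with its 3 probes. Slamf1 was at least 1.51-fold higher and Flt3 at least 1.76-fold lower without serum.

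Neutrophil genes differed between the media as well. S100a9 was at least 71.5-fold, S100a8 at least 12.2-fold and Chil3 at least 11.7-fold lower without serum, and 6 members of the neutrophil and monocyte list were detected on the serum array only. The list's median over 8 measured members was -0.14, with -0.69 when those members entered at their bound and 0.10 in the brighter part of the genes. Cd68, a lysosomal protein of macrophages, differed by -2.21 (or -1.40 with its other probe) and Gzmb by -2.18. The other bright genes with the largest negative differences were Lpar2 (-2.31), Aldh5a1 (-2.27), Tnni2 (-1.99) and Pik3ap1 (-1.84). Ric3 and Gpm6b were at least 16.0-fold and 9.68-fold higher without serum, and Hoxd11 by at least 3.17 (log2). Megakaryocyte markers had a median of -0.40, erythroid markers -0.15, multipotent progenitor markers -0.14, B cell markers 0.33, T and NK cell markers 0.04 and stromal and endothelial markers 0.01.

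Between the media, 507 of 13427 genes measured on both arrays were at least 2-fold higher without serum and 404 at least 2-fold lower, with 212 and 226 further genes at bounds of at least 2-fold higher and lower. Normexp background correction gave 149 and 102 genes, and higher genes made up 55.7% of the differences, or 49.6% without the filter on dim probes. Among named genes other than Fasn, normexp took Slc16a3 (0.82), Pdzk1ip1 (0.81), Txnip (0.96), Pes1 (-0.88), Polr1b (-0.79), Hoxb5 (0.55), Arl4c (-0.60) and Id2 (-0.49) below 2-fold, and the mean of probes did so for Mvk (0.47). Normexp gave smaller differences, still past 2-fold, among others for Aldoc (2.85), Ifi44 (1.49), Lss (1.19) and Skil (-1.24). Across genes, the correlation of levels was 0.975 between the cultured arrays, 0.930 between the serum-free and fresh arrays and 0.925 between the serum and fresh arrays. Genes are not independent replicates.

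**Figure D2:**
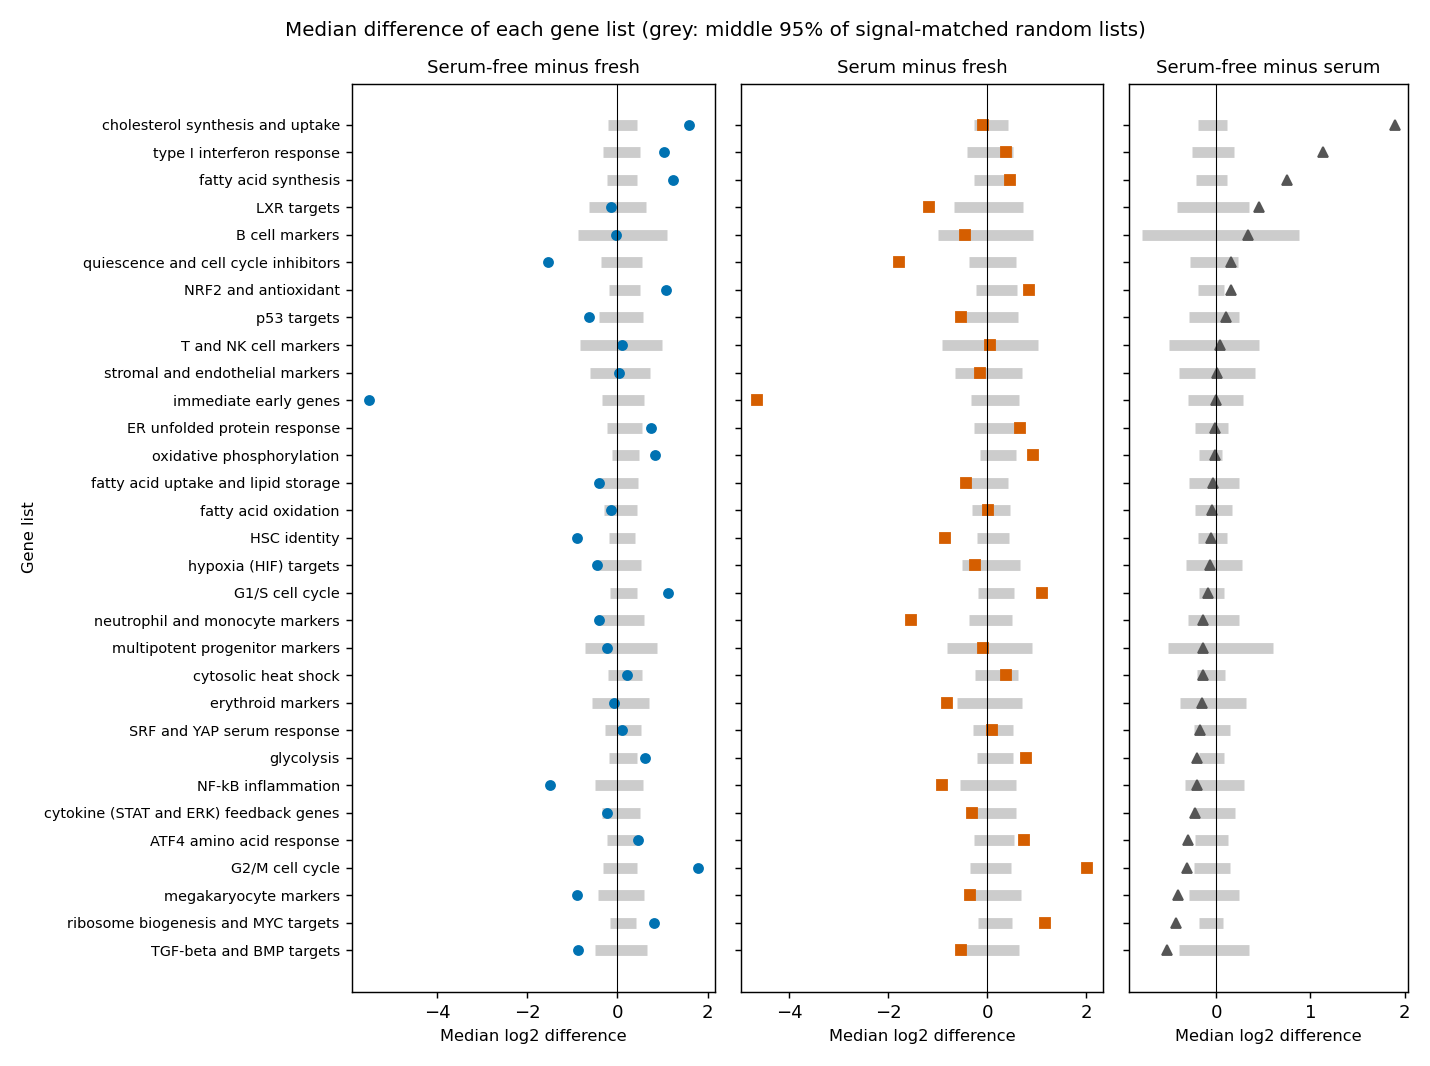
Median log2 difference (horizontal axis) of each gene list with at least 3 measured members, for serum-free minus fresh (blue circles), serum minus fresh (orange squares) and serum-free minus serum (grey triangles), with grey bars for the middle 95% of 10000 random lists matched on signal. Immediate early genes lie at -5.51 and -4.65 against the fresh array and at 0.00 between the media, whereas the cholesterol list lies at 1.60, -0.08 and 1.90.

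Both cultures differed from fresh cells in many of the same genes. Of 13173 genes measured on all 3 arrays, 1205 were at least 2-fold higher in both media, including S100a4, Mthfd2 and Nup43, and 854 at least 2-fold lower in both, including Fosb, Jun and Dusp1. Only 11 genes differed at least 2-fold in opposite directions. Independent lists of these sizes would share 230 higher and 131 lower genes. Both differences use the same fresh array, which alone makes them correlate. The correlation across genes was 0.84, against 0.50 in 100 simulations of unchanged arrays, in which 139 genes were higher in both and 139 lower in both. The covariance was 0.73 against 0.15 in the simulations, a difference of 0.58. The fresh condition had 1 array and could not be split, so part or all of the excess may come from the shared array. The simulations give the fresh array only the scatter seen between both cultured arrays. They therefore cannot separate an effect of culture from a deviation of the fresh array.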

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

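The test of heat shock genes below was chosen after the result was seen, as was the alternative with a correction for GC content and signal. Each difference here was not tested, since each medium had 1 array.

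The cholesterol synthesis and uptake list had a median of 1.60 without serum and -0.08 with serum against the fresh array, where the latter is near 0 and turned to 0.12 in the brighter part of the genes. Scd1 differed by 4.87 without and -1.60 with serum, and the interferon-induced gene Oasl2 by 1.56 and -1.06. Both negative values were below 2-fold with normexp, at -0.72 and -0.77.

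Between the media, the list medians were 1.90 for cholesterol and 0.75 for fatty acid synthesis, the latter with 8 of 27 members at least 2-fold higher without serum and 6 below 0. The neutrophil genes S100a9 and S100a8 were at least 71.5-fold and 12.2-fold lower without serum in the same comparison. Scaling between arrays as the whole cause is argued against, since the lower of both list medians stayed at 0.67 or above over quantile, median, detected-probe and normexp settings. A trend with probe GC content and signal is argued against as well, because the lower median was 0.85 after its correction, which ended 61 of 911 differences of at least 2-fold and added 56. The effect of 1 culture well or 1 array cannot be told apart from that of serum, since the number of arrays per medium is 1, and serum itself stays open as the biological explanation the design names.

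More genes were detected on the fresh array only (2220) than on the serum-free array only (450). With 1 common cutoff of scaled signal on both arrays, 26.7% of that surplus of 1770 genes was kept, which is consistent with a higher background cutoff on the serum-free array as a source of most of it. The spread of the negative controls, per the file headers, was wider on the serum-free array, at 15.4 intensity units, than on the fresh array. A change of expressed genes with culture cannot be told apart from it for the rest, because 22.0% of the fresh-only genes had a bound of at least 2-fold, neither most of them nor a negligible share.

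Immediate early genes were lower on both cultured arrays. Scaling is argued against, since the list medians stayed at or below -4.30 over the same 4 settings and both media. Handling stress of the fresh cells during isolation and sorting cannot be told apart from a loss of these transcripts in culture. The same limit holds for the quiescence, NF-kB, p53 and TGF-beta lists, which were set against the same fresh array. Of the 5 inducible heat shock genes on the array, 3 (Hspa1a, Hspb1 and Dnajb1) were at least 2-fold lower on both cultured arrays. Hsph1 (0.15, or -0.16 with its other probe, without serum and 0.38 with serum) and Bag3 (0.05 and -0.29) were not. This choice of genes was made with their values known and decides nothing. The median of the whole heat shock list was 0.22 without and 0.38 with serum.

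Probes outside the comparisons were counted as well. On the fresh array, 43 of 137 spike-in control probes carried the flag for a signal well above background, although the labels name no spike-in RNA. Of 7801 genomic interval probes measured on both the serum-free and fresh arrays, 944 were at least 2-fold higher without serum and 638 at least 2-fold lower. The share of higher ones, 12.1%, was close to the 12.4% over genes. The largest difference was for the interval on chromosome 1 from 183783306 to 183834531 (mm9, forward strand), at 4.71 without and 5.39 with serum.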

How the results depend on the processing

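Values with no replicate have no spread, so a list median counted as moved where it shifted by more than the distance from the middle to the edge of its random range, a count where it changed over 1.5 times, and a gene where it shifted by more than its software error. No paired analysis was possible because each condition had 1 array and the labels give no replicate numbers that pair samples, and no array could be left out. Counts over all named targets, members at their bound and the GC and signal correction were chosen after seeing the data. Quantile normalization, median scaling, scaling on detected probes, the authors' deposited values and the GC and signal correction moved no list, count or named gene they were run on. Of 1015 list results, 992 held, 22 moved and 1, of a list outside its random range, reversed. Medians inside the random range, mostly near 0, turned sign more often, in 64 results, including megakaryocyte genes in serum minus fresh. The total of 1015 includes settings that could hardly move a list. The authors' deposited values lie within 0.01 of the main values, and median and detected-probe scaling shift all genes of a comparison alike. For the 36 largest measured differences of named genes, 35 of 324 results moved, 29 of them with normexp, and none changed sign. Of 77 differences of chosen lipid, interferon, immediate early and sort marker genes, 9 took both signs over the alternatives, among them Mecom and Scd2 in serum minus fresh. Median scaling put the median of all genes at 0.13 for serum-free minus fresh and 0.11 for serum minus fresh, and detected-probe scaling at -0.07 and -0.12. Of 93 list results, 48 lay outside the random range with and 48 without matching on signal, and 4 changed side. Glycolysis and NRF2 genes between the media lay outside it only with matching, and ATF4 genes in serum-free minus fresh and TGF-beta targets in serum minus fresh only without.

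Below, the order is serum-free minus fresh, serum minus fresh, serum-free minus serum. At least 3-fold higher and lower genes numbered 574 and 534, 692 and 650, and 150 and 86, fewer by the rule's construction. Without the filter on dim probes, more genes enter, and the counts were 2644 and 3321, 2977 and 3494, and 1635 and 1659. In the brighter part of the genes, fewer enter, and they were 827 and 534, 1082 and 613, and 110 and 83. With normexp they were 906 and 687, 1128 and 794, and 149 and 102, since its offset shrinks differences of dim genes. All named targets gave 770 higher genes in serum-free minus serum. Both differences against the fresh array had a correlation of 0.743 and 2113 genes lower in both without the filter, 0.899 with 673 higher and 375 lower in the brighter part, and 667 higher and 482 lower with normexp.

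For list medians moved by normexp, serum-free minus fresh gave 0.79 for fatty acid synthesis, 1.20 for cholesterol, 1.35 for G2/M, -4.44 for immediate early and -0.90 for NF-kB genes. Serum minus fresh gave 1.54 for G2/M and -0.75 for neutrophil genes, and serum-free minus serum 1.28 for cholesterol genes. Without the filter, neutrophil genes gave -2.64 in serum-free minus fresh and -1.11 in serum-free minus serum, NF-kB genes -0.73 in serum-free minus fresh and -0.27 in serum minus fresh, and in serum minus fresh ATF4 genes gave 0.33 and megakaryocyte genes 0.23. In the brighter part, fatty acid uptake and storage genes turned to 0.046 in serum-free minus fresh, where erythroid genes gave -1.48 and interferon genes 1.54. There, megakaryocyte genes gave 0.33 in serum minus fresh and LXR targets 0.97 in serum-free minus serum. The mean of probes gave -1.63 for NF-kB genes in serum minus fresh. Members at their bound gave -2.58 for neutrophil and 1.54 for interferon genes in serum-free minus fresh, and -0.69 for neutrophil genes in serum-free minus serum. Except where the construction is named, the cause was not tested.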

Other observations

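The gene families and genes in this part were chosen after their values were seen, and no explanation of them was tested.

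Most replication-dependent histone genes were higher in culture, with 18 of 34 measured genes at least 2-fold higher without serum (median 1.04) and 25 of 35 with serum (median 1.27). Their medians stayed above 0 under quantile, median, detected-probe and normexp settings, from 0.94 to 1.14 without and 1.13 to 1.37 with serum. Both H1f2, a linker histone gene, and H2bc4, a histone H2B gene, went the other way. H1f2 was 45.9-fold lower without serum (-5.52) and 51.0-fold lower with serum (-5.67), and H2bc4 21.6-fold and 37.8-fold lower (-4.43 and -5.24). Each was read by 1 probe, and histone genes are close enough in sequence that probes can share signal, so single genes of this family are uncertain.

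Beta-globin and alpha-globin probes moved apart. Beta-globin genes are near-identical in sequence, so the Hbb-bt and Hbb-b2 probes can share signal and are not independent. Hbb-bt was 39.0-fold higher without serum and 56.9-fold higher with serum than in fresh cells, and Hbb-b2 was at least 15.2-fold and 25.2-fold higher, while Hba-a1 differed by -1.63 and -1.36. The S100 family was split in the same way. S100a4 differed by 4.95 in both media and S100a6 by 3.26 and 3.23, while S100a8 differed by -1.33 and S100a9 by -1.86 with serum and both were not well above background without it. Lyz2, a myeloid lysozyme gene, differed by -0.99 without and -1.14 with serum. MHC class II genes had medians of -0.73 and -1.02 over 8 measured genes, with H2-Ab1 at -2.80 without and -1.91 with serum, while H2-DMb2 was at least 20.2-fold higher without serum. The metallothionein gene Mt2 differed by -1.61 without and 0.99 with serum, and Mt1 by 0.86 and 1.53. The aldolase gene Aldoc differed by 0.58 without and -3.30 with serum.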
